A study of Mus musculus with 8 samples.

How the data were processed

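RNA from thymus lobes of 8 mice of the C57BL/6NTac strain was measured on Affymetrix arrays, with 4 mice flown on the space shuttle for 13 days and 4 ground-control mice kept in the same kind of animal enclosure module. Per the labels' protocols, total RNA was extracted with Trizol and 6 µg of it was made into biotin-labelled cRNA, the amplified copy that is hybridised to the array. The deposited values are log2 expression values, and the submitters' processing notes name RMA (background correction, quantile normalization between arrays and a median-polish summary of the probes of each probe set) and limma. The versions of these tools, the genome build and any filter on probe sets were not given in the sources used here. The values ran from 1.72 to 14.03 over the probe sets tested, and the median per array lay between 6.01 and 6.10, so they were used on the log2 scale as deposited.

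The table held 35557 probe sets with plain numbers as identifiers. The lowest unbroken run of identifiers, 6614 probe sets, had no gene in the annotation and was taken to be the array's controls and left out, although the table does not mark it as such. This choice was made after seeing the data. Of the remaining 28943 probe sets, 23410 were in the platform annotation, 21789 of them with 1 gene and 1621 with several, and 5533 were tested without a gene name. Symbols were brought up to date through their Entrez identifiers with the RefSeq gene table of assembly GRCm38.p6, where 21698 matched. A gene was represented by its probe set of highest mean over all 8 arrays, using only probe sets with a single gene, which gave 19938 genes, 999 of them with more than 1 probe set. No gene was named from a probe set with several genes.

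Spaceflight was compared with ground control in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, all 8 arrays, no replicate block), with Benjamini-Hochberg adjustment and a threshold of 0.05. Every difference is spaceflight minus ground control, and every adjusted p of a gene comes from this limma fit. Before the data were examined, 32 gene lists were fixed, 17 for processes and 15 for cell types. They held 570 distinct genes, of which 526 were measured. Process lists covered heat shock chaperones, cold-inducible RNA-binding proteins, glucocorticoid response, the unfolded protein response of the endoplasmic reticulum (ER), cell cycle, p53 and apoptosis, interferon response, MHC class II presentation, T cell receptor signalling, immediate early genes of negative selection, circadian clock, extracellular matrix, cholesterol biosynthesis, hypoxia and glycolysis, antioxidant response, ribosome biogenesis and oxidative phosphorylation. The cell type lists covered double-negative, double-positive and mature single-positive thymocytes, cortical and medullary epithelium, dendritic cells and macrophages, B and plasma cells, red cells, neutrophils, fat cells, muscle, fibroblasts, endothelium, lymph node, and parathyroid and thyroid. Each list was tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over the 32 lists, and with an exact two-sided permutation test of its mean over the 70 ways of assigning the 8 arrays, whose smallest possible p is 0.0286. Members were also tested with the p-values adjusted over the list alone. The heat shock, cold-inducible and glucocorticoid lists were written knowing that stress-response genes had been put forward for these samples, so their counts are not independent evidence of direction. A further 5 lists (fatty acid synthesis, fat cell markers outside that pathway, airway epithelium, squamous epithelium and liver) were drawn up once the data had been seen.

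The rule for naming genes was fixed before the data were examined. It took the 10 genes with the largest differences in each direction among those at an adjusted p under 0.05, the 5 of smallest p in a direction where fewer than 5 passed, and up to 4 members of smallest p of each list (the whole list where it had at most 5 measured members). Arntl, Clock, Acss2, Scgb1a1 and Krt13 fall outside it and were chosen after their values were seen, as were Acaca, Elovl3, Scd1 and Ivl, which are named only as members of lists.

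The labels number the mice of each group but do not say that numbers were shared on purpose. No 2 arrays were identical. The number of arrays limits the precision. The procedure was tested on simulated data for this comparison, with 200 of 19938 genes changed: it recovered 28% of genes changed by 0.5 on the log2 scale, 94% of those changed by 1 and 100% of those changed by 1.5 or 2, with 7 false calls among 176. A list shifted by 0.5 was called and 0 of 31 unchanged lists were. The simulated noise was independent between probe sets. In the real arrays the estimated correlation between genes was 0.85 for the MHC class II list. The simulation therefore does not show how often camera calls unchanged lists of correlated genes. Alternatives were other centring, repeated quantile normalization, level filters, variance options of limma, array weights, a replicate block, other thresholds, the mean of a gene's probe sets, other list tests and leaving out each array. After seeing the data, leaving out spaceflight replicates 1 and 3 together, including the run of control identifiers, and using only probe sets with a single gene were added. Plots were drawn with matplotlib 3.10.9.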

Results

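Thymus gene expression was measured in 4 mice, 8 weeks old, flown on the shuttle for 13 days and in 4 ground-control mice, with a single array per mouse. The thymus is the organ in which T cells mature, supported by cortical and medullary epithelial cells. The comparison asks which genes differ in this organ after the flight. Spaceflight replicates 1 and 3 stood apart from the other 6 arrays. The interquartile range of their log2 values was 2.43 in both, against 2.68 to 2.95 in the others. Their correlation with the other 6 was 0.954 to 0.984, where the other 6 correlated with each other at 0.986 to 0.994. With all arrays, the median difference between groups ran from 0.11 among dim genes to -0.14 among bright genes. Without these 2 arrays it stayed between -0.03 and 0.01 at every level.

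After spaceflight the thymus held more transcript of Rbm3, which encodes an RNA-binding protein induced by mild cold, and less of Hsph1, which encodes a large heat shock protein of the Hsp110 family. Rbm3 rose 2.65-fold, from 10.61 ± 0.17 to 12.01 ± 0.09 (log2, mean ± SD, n = 4 each; limma adjusted p = 0.00276). Hsph1 fell 3.72-fold, from 9.51 ± 0.21 to 7.62 ± 0.29 (limma adjusted p = 0.00276). Another 3 chaperone genes fell. Hsp90aa1, the inducible cytosolic Hsp90, fell by 0.88 ± 0.11 (log2 difference ± SE; adjusted p = 0.0213). Stip1, a co-chaperone that joins Hsp70 to Hsp90, fell by 0.88 ± 0.12, and Fkbp4, an Hsp90 partner in steroid receptor complexes, fell by 0.93 ± 0.13 (adjusted p = 0.0423 for both).

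Cxcl10, a chemokine induced by interferon, fell 2.83-fold, from 8.94 ± 0.12 to 7.44 ± 0.34 (mean ± SD, adjusted p = 0.014). Acly, the enzyme that makes cytosolic acetyl-CoA for lipid synthesis, fell by 1.23 ± 0.14 (adjusted p = 0.0151). Ptger3, a receptor for prostaglandin E2, fell by 1.25 ± 0.15 (adjusted p = 0.0172), and Wdr78, a gene of a WD-repeat protein, fell by 0.95 ± 0.10 (adjusted p = 0.014). Slc28a2b, a nucleoside transporter gene, rose by 1.18 ± 0.16 (adjusted p = 0.048), and its value is uncertain because it has a close paralog. Genes of smallest p among higher genes that did not pass were Cirbp, Olfr920 and Ciart. Cirbp, another cold-inducible RNA-binding protein, differed by 1.27 ± 0.20 (adjusted p = 0.0744), the olfactory receptor Olfr920 by 0.64 ± 0.11 (adjusted p = 0.112), and Ciart, a repressor in the circadian clock, by 0.72 ± 0.13 (adjusted p = 0.123).

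In all, 10 genes were at a limma adjusted p under 0.05, 2 higher and 8 lower. They came from 14 probe sets, 4 higher and 10 lower, of which 9 changed at least 2-fold (4 higher, 5 lower). Rbm3 was called by 3 probe sets (differences from 1.30 to 1.41), as was Hsp90aa1 (from -1.02 to -0.85). The probe set numbers at the gene level were 10556113 (Rbm3), 10475502 (Slc28a2b), 10535904 (Hsph1), 10378848 (Hsp90aa1), 10465604 (Stip1), 10548194 (Fkbp4), 10531415 (Cxcl10), 10391146 (Acly), 10497079 (Ptger3) and 10514713 (Wdr78). Rbm3 and Hsph1 passed whichever array was left out, Cxcl10 passed in 4 of the 8 cases, Acly and Wdr78 in 3, Ptger3, Hsp90aa1 and Stip1 in 1, and Fkbp4 and Slc28a2b in 0. The count was 6 genes (2 higher, 4 lower) without spaceflight replicates 1 and 3, and centring arrays on their 75th percentiles gave 3 genes (1 higher, 2 lower) and 6 probe sets (3 higher, 3 lower).

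**Figure D1:**
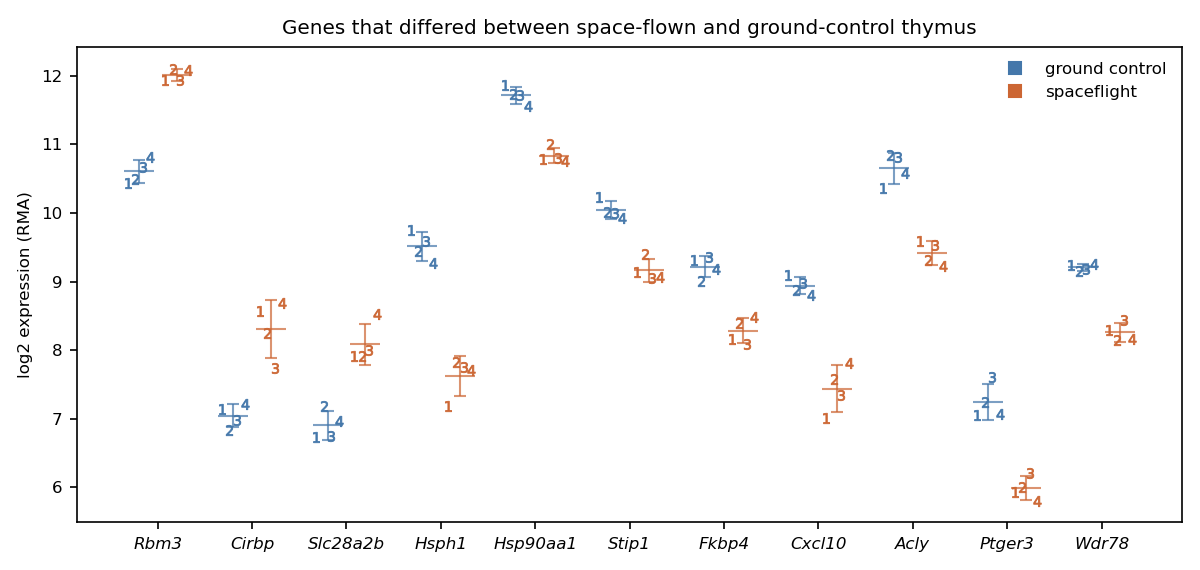
Log2 expression of the 10 called genes and Cirbp in each array (digits are replicate numbers, blue for ground control and orange for spaceflight), with the mean as a horizontal mark and the SD as the bar, n = 4 per group. The 4 spaceflight values of Rbm3 lie between 11.93 and 12.11, above all ground-control values (10.44 to 10.81), and those of Hsph1 between 7.19 and 7.83, below the ground-control values (9.27 to 9.76).

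Heat shock chaperones fell as a group. The mean of each of the 24 measured members was lower in spaceflight, 4 of them (Hsph1, Hsp90aa1, Stip1 and Fkbp4) fell over all genes tested, and 19 fell when adjusted over the list alone. The list mean was -0.65 ± 0.12 (± SE). Camera gave an adjusted p of 1.16e-23, against an adjusted p of 0.301 with an estimated correlation between genes, and the exact permutation p was 0.0286. Without spaceflight replicates 1 and 3 the mean was -0.50 and 14 members fell when adjusted over the list alone. Of the 5 cold-inducible RNA-binding genes, Rbm3 rose over all genes and Cirbp also rose when adjusted over the list alone. Srsf5 (0.30), Srsf2 (-0.20) and Rtn3 (-0.08) did not pass. The mean of this list was 0.54 ± 0.07 (camera adjusted p = 0.00163; adjusted p = 0.301 with an estimated correlation; exact permutation p = 0.0286). Its median was 0.30, Rbm3 and Cirbp carried the mean, and camera on ranks did not call it (adjusted p = 0.203). Both lists were chosen with knowledge of stress genes put forward for these samples and are not independent evidence of direction.

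Chaperones and folding enzymes of the ER were lower, with a list mean of -0.34 ± 0.11. When adjusted over the list alone, 9 of 21 fell, and 0 fell over all genes. Examples were Calr, a calcium-binding ER chaperone (fell by 0.58), Sdf2l1 (fell by 0.76), Hyou1 (fell by 0.56) and the disulfide isomerase Pdia6 (fell by 0.57). Cholesterol biosynthesis genes had a mean of -0.35 ± 0.11, and 6 of 18 fell when adjusted over the list alone. Among them were Insig1, a sterol-regulated inhibitor of the pathway (fell by 0.85), and the pathway enzymes Idi1 (fell by 0.77), Sc5d (fell by 0.49) and Hmgcs1 (fell by 0.55). Ribosome biogenesis genes had a mean of -0.27 ± 0.07, and 11 of 21 fell when adjusted over the list alone. The nucleolar proteins Nop56 (fell by 0.48), Bop1 (fell by 0.39), Gnl3 (fell by 0.43) and Mybbp1a (fell by 0.53) were among these. Camera called the ER, cholesterol and ribosome lists (adjusted p = 1.63e-08, 6.59e-07 and 6.59e-07), and each had an exact permutation p of 0.0286. None was called with an estimated correlation (adjusted p = 0.439, 0.4 and 0.4). In each list spaceflight replicate 1 or 3 was the lowest array. Without both, 0 of 21 ER genes, 1 of 18 cholesterol genes and 0 of 21 ribosome biogenesis genes fell when adjusted over the list alone, with means of -0.17, -0.25 and -0.17.

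Markers of cortical thymic epithelium, the cells that support the double-positive stage, were lower, with a mean of -0.36 ± 0.10. When adjusted over the list alone, 7 of 13 fell, and 0 fell over all genes. Foxn1, the transcription factor that thymic epithelium depends on, fell by 0.63, Psmb11, the cortex-specific proteasome subunit, by 0.79, Dll4, the Notch ligand that directs T lineage entry, by 0.47, and Tbata by 0.72. Camera gave an adjusted p of 1.94e-06, the adjusted p was 0.4 with an estimated correlation, and the exact permutation p was 0.0286. Without spaceflight replicates 1 and 3 the mean was -0.20 and 3 members fell when adjusted over the list alone. Medullary epithelium had a mean of -0.29 ± 0.13. When adjusted over the list alone, 3 of 16 fell, the keratins Krt5 (fell by 0.66) and Krt17 (fell by 0.75) and the costimulatory ligand Cd80 (fell by 0.42, while its other probe set differed by 0.024). Its camera adjusted p was 0.0024, with an adjusted p of 0.445 under an estimated correlation and an exact permutation p of 0.0571. The call ended without replicates 1 and 3 (adjusted p = 0.173).

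Of the 32 lists, camera called 18, with 2 higher and 16 lower. With all arrays, bright genes as a whole already differed by a median down to -0.14. Lists such as p53 (mean -0.15) and oxidative phosphorylation (-0.16) lay near that shift. With an estimated correlation camera called 0, and 2 lists (heat shock and cold-inducible) were at an unadjusted p under 0.05. Limma's fry, which asks whether a list's genes move in a single direction on balance, called the same 2 lists (adjusted p = 0.0124 and 0.00694). The exact permutation test reached its smallest p, 0.0286, for 6 lists, where 0.914 would be expected by chance. These were heat shock, cold-inducible, ER, cholesterol, ribosome biogenesis and cortical epithelium, and none passed after adjustment over 32 lists (permutation p adjusted = 0.152). All lists were scored on the same arrays, so they are not independent and the excess over 0.914 is not itself a test. The heat shock and cold-inducible lists were also written with knowledge of these samples. Camera called these 6 among 11 lists without spaceflight replicates 1 and 3, and none of the 11 with an estimated correlation (smallest adjusted p = 0.422).

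**Figure D2:**
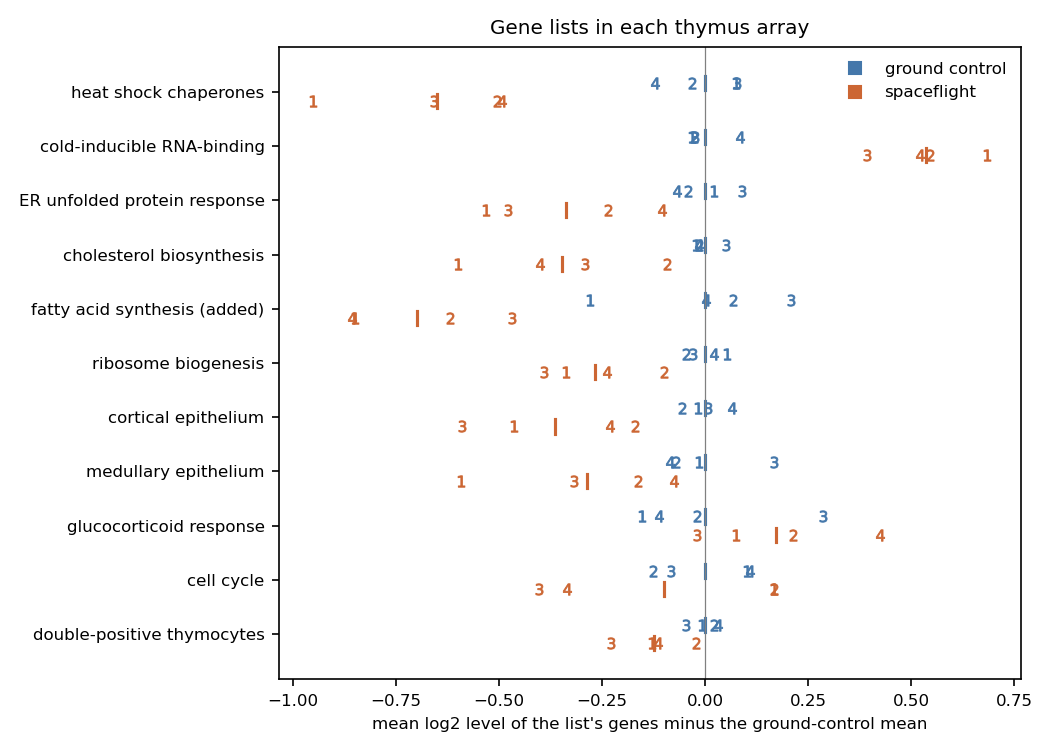
Mean log2 level of the genes of a list in each array minus the ground-control mean (horizontal axis), for 11 lists, with digits for replicates, vertical marks for group means, blue for ground control and orange for spaceflight. All 4 spaceflight arrays lie between -0.95 and -0.49 for heat shock chaperones and between 0.39 and 0.69 for cold-inducible genes, while cell cycle values of the groups overlap.

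Glucocorticoid response genes were higher by camera, with a mean of 0.17 ± 0.14, though the arrays of the 2 groups overlapped. When adjusted over the list alone, 3 of 21 rose: the metallothioneins Mt1 (0.75) and Mt2 (0.97), which bind metal ions, and Txnip (0.48), an inhibitor of thioredoxin. Fkbp5, a target of the glucocorticoid receptor, differed by 0.54 ± 0.21 and did not pass. The camera adjusted p was 0.000829, the adjusted p with an estimated correlation was 0.557, and the exact permutation p was 0.257. Leaving out single arrays gave means from 0.089 (without spaceflight replicate 4, adjusted p = 0.0387) to 0.27, each called by camera. Without spaceflight replicates 1 and 3 the mean was 0.32 and 5 members rose when adjusted over the list alone. This list too is not independent evidence of direction.

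Interferon response genes had a mean of -0.25 ± 0.11. Cxcl10 and Rtp4 (fell by 0.45) were the 2 of 25 that fell when adjusted over the list alone, and Gbp4 (-0.31) did not pass. Of p53 and apoptosis genes (mean -0.15 ± 0.08), 3 of 19 fell when adjusted over the list alone: Phlda3 (fell by 0.81), Zmat3 (fell by 0.42) and the death receptor Tnfrsf10b (fell by 0.40). In the hypoxia and glycolysis list (mean -0.21 ± 0.11), P4ha1, a collagen prolyl hydroxylase (fell by 0.93), and the hexokinase Hk2 (fell by 0.64) fell when adjusted over the list alone. In the antioxidant list (mean -0.18 ± 0.15) Me1, the cytosolic malic enzyme, fell by 1.30. No member passed in immediate early genes (mean -0.15 ± 0.09), extracellular matrix (-0.15 ± 0.20) or oxidative phosphorylation (-0.16 ± 0.11). Camera called each list of this paragraph as lower (adjusted p from 0.000215 to 0.0419), but none with an estimated correlation (adjusted p from 0.557 to 0.789) and none without spaceflight replicates 1 and 3. All but the interferon call also depended on single arrays. Without spaceflight replicate 1 the means were -0.0956 for p53 (adjusted p = 0.118), -0.11 for hypoxia (0.054), -0.0582 for antioxidant (0.672) and -0.0614 for oxidative phosphorylation (0.315). Extracellular matrix was at -0.0116 without ground-control replicate 3 (adjusted p = 0.993), and immediate early genes at -0.10 without spaceflight replicate 3 (adjusted p = 0.12).

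Some circadian clock genes were higher. When adjusted over the list alone, 3 of 17 rose and 0 fell: Ciart (0.72), the clock-output transcription factor Tef (0.44) and Per3 (0.46). Dbp, another output factor, differed by 0.53 ± 0.19 and did not pass, nor did Clock (-0.45 ± 0.16) and Arntl (-0.26 ± 0.12), the activators of the loop. The list mean was 0.06 ± 0.09 and camera did not call it (adjusted p = 0.108), while fry's mixed test of change in either direction gave an adjusted p of 3.45e-06 and called 11 of the 32 lists. Without spaceflight replicates 1 and 3, 6 members rose and 0 fell when adjusted over the list alone, and camera called the list as higher, as it did in 3 of the 8 cases without a single array (mean 0.18 without both, adjusted p = 0.000939; adjusted p = 0.535 with an estimated correlation).

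Lists of proliferation and of early thymocyte stages did not pass with all arrays. Cell cycle genes had a mean of -0.10 ± 0.17, with Ccne2, a cyclin of S-phase entry, at -0.68 ± 0.18, and 0 of 30 passed when adjusted over the list alone. Double-positive thymocyte markers had a mean of -0.12 ± 0.05, with Rag2 at -0.25 ± 0.10 and Cd8a at -0.22 ± 0.10, and double-negative markers had a mean of -0.11 ± 0.10. T cell receptor signalling genes had a mean of -0.05 ± 0.08, and 1 of 25, the inhibitory receptor Ctla4, rose when adjusted over the list alone (0.68). MHC class II genes had a mean of -0.18 ± 0.19. Camera adjusted p-values for these lists ran from 0.054 (double-positive) to 0.454 (double-negative). Leaving out a single array made camera call the cell cycle list as lower in 4 of 8 cases, double-positive markers in 3 and MHC class II in 2, and array weights made it call the first 2. Mature single-positive markers had a mean of -0.21 ± 0.13 and were called (adjusted p = 0.0325; adjusted p = 0.636 with an estimated correlation), with 0 of 13 members passing. That call ended in 4 of the 8 cases in which a single array was left out (highest adjusted p = 0.135, without spaceflight replicate 3) and without spaceflight replicates 1 and 3 (adjusted p = 0.794). It also ended with repeated quantile normalization (adjusted p = 0.149).

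Among markers of other cells, fat cell genes (mean -0.34 ± 0.27) and muscle genes (-0.33 ± 0.36) were called as lower (adjusted p = 0.00163 and 0.0198; adjusted p = 0.636 and 0.739 with an estimated correlation). The hormones Retn (fell by 0.83) and Lep (fell by 0.75) and the adipogenic factor Pparg (fell by 0.60) fell when adjusted over the fat list alone. Without spaceflight replicate 1 the means were -0.10 and -0.04 and neither list was called (adjusted p = 0.315 and 0.901). Over the 8 cases without a single array, camera called the fat list in 7 and the muscle list in 5. Without both replicates 1 and 3 the muscle list was called again (mean -0.21, adjusted p = 0.0134; adjusted p = 0.839 with an estimated correlation). Dendritic cell and macrophage markers (mean -0.13 ± 0.19), B and plasma cell markers (-0.11 ± 0.17), red cell markers (-0.30 ± 0.10) and neutrophil markers (-0.16 ± 0.10) were not called with all arrays. Nor were those of fibroblasts (-0.22 ± 0.26), endothelium (-0.12 ± 0.23), lymph node (0.01 ± 0.16), and parathyroid and thyroid (-0.16 ± 0.17). Without a single array, camera called red cells and fibroblasts as lower in 3 of 8 cases each, and dendritic cells and macrophages in 1. Without spaceflight replicates 1 and 3 camera called dendritic cells and macrophages as higher (mean 0.15, adjusted p = 0.00861; adjusted p = 0.795 with an estimated correlation). Red cells were then called as lower (mean -0.29, adjusted p = 0.0115; adjusted p = 0.422 with an estimated correlation). Mmp9 of the neutrophil list (fell by 0.63) and Tshr of the thyroid list (fell by 0.95) were the single members that fell when adjusted over those lists alone. The lymph node list had a mean above 0, a median of -0.07 and a test direction of lower, and the parathyroid and thyroid list had a median of 0.01. Lists of airway epithelium (-0.87 ± 0.67) and squamous epithelium (-0.62 ± 0.49), drawn up after the data were seen, had no member that passed, and spaceflight replicate 1 was the lowest array of both.

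**Figure D3:**
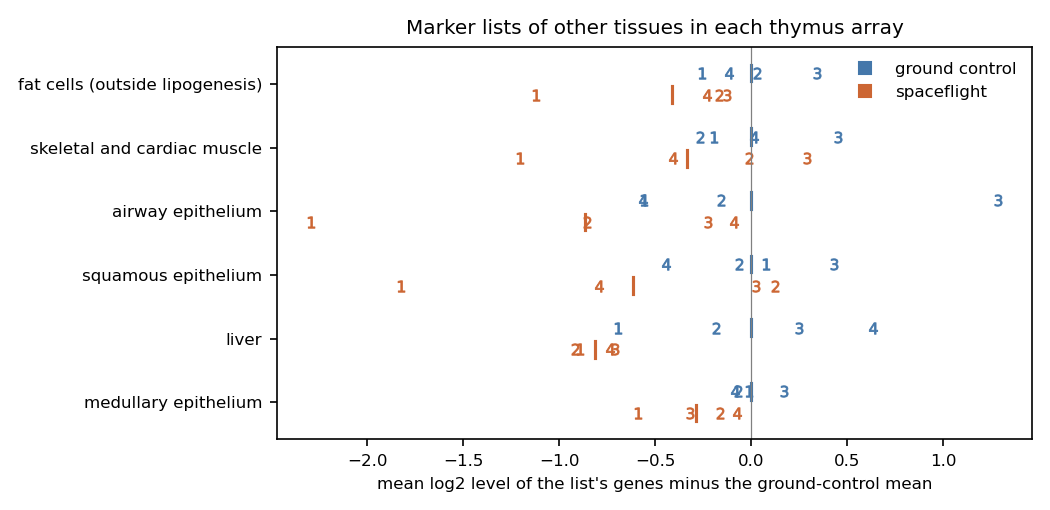
Mean log2 level of marker lists of other tissues in each array minus the ground-control mean (horizontal axis), with digits for replicates, vertical marks for group means, blue for ground control and orange for spaceflight. Spaceflight replicate 1 lies at -2.29 for airway epithelium, -1.82 for squamous epithelium and -1.20 for muscle, while the liver list lies between -0.92 and -0.71 in all 4 spaceflight arrays.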

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

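The test of attached tissue below was chosen only after fat markers had been seen. In 224 tests of a group of 4 arrays, 10 values lay far from the other 3 by Dixon's criterion, where about 11.2 would be expected by chance, since chance marks about 1 group in 20.

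Scgb1a1, which encodes the secretory protein of airway club cells, was at 3.78 in spaceflight replicate 1 and between 10.65 and 11.51 in the other 3 spaceflight arrays. In the same array the fat marker Plin1 was at 7.32 (8.40 to 8.60 in the others), the mean of the fat cell list at 8.14 (9.09 to 9.15) and that of fat markers outside fatty acid synthesis at 7.92 (8.81 to 8.91).

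Slc28a2b was at 8.53 in spaceflight replicate 4, against 7.91 to 7.99 in the other spaceflight arrays. Tnfrsf10b was at 5.80 in ground-control replicate 4, against 5.94 to 5.97 in the others, and the cold-inducible list mean was at 9.89 in that array, against 9.77 to 9.78. Ground-control replicate 3 was high in the means of the cholesterol list (7.72, against 7.64 to 7.65), the double-negative thymocyte list (6.81, against 6.61 to 6.63) and the endothelium list (7.30, against 6.50 to 6.56).

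The low Scgb1a1 value belonged to a wider pattern, in which genes of airway and squamous epithelium (such as the keratin Krt13, at 5.52 against 9.24 to 11.38) were low in spaceflight replicate 1, by a median of -0.86 from the other spaceflight arrays. Loss of medullary epithelium, which makes such transcripts itself, was argued against as the whole cause. Medullary regulators and receptors deviated by a median of only -0.22 (95% bootstrap interval over the 7 genes -0.47 to -0.02). This interval does not measure spread between lobes. A smaller loss stays open, because the medullary list of 16 genes was also lowest in this array of all 8 (6.42, against 6.69 to 6.94 in the other spaceflight arrays). Its mean deviation was -0.41, and -0.42 for the 13 genes that are not on the squamous list. A straight line fitted over all genes against the mean of the other spaceflight arrays predicted 10.3% of the fall from the narrower range of that array. This share may be too low, because that mean includes spaceflight replicate 3, whose interquartile range was as narrow (2.43). Less attached tissue on this lobe may account for it. Muscle and fat markers lay under the lowest of the other 7 arrays too (differences of -0.796 and -0.861), as that explanation needs. Being lowest was not specific to such markers. This array was also the lowest for oxidative phosphorylation (-0.47 from the ground-control mean) and double-negative thymocytes (-0.33), though not for double-positive thymocytes. The check therefore cannot tell less attached tissue from a wider fall in this array. Of the squamous genes, Krt5, Krt14 and Ivl are also on the medullary list. No other biological explanation for this array was tested.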

How the results depend on the processing

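The alternatives without both spaceflight replicates 1 and 3, with the control identifiers, and with single-gene probe sets only were chosen after seeing the data. The cause of a move was not tested, except that fewer arrays, fewer probe sets or another threshold changes a count by construction. Outside the cases below, the counts stayed within 1.5 times their value, and the differences of named genes kept their direction under every alternative run (Krt14, Ivl, Acaca, Elovl3 and Scd1 were not followed). Apart from leaving out single arrays, 884 values of named genes kept their side of the threshold, 28 lost a call and 13 gained it, and 411 values of lists kept theirs, 67 lost a call and 16 gained it. A further 14 values of lists turned direction, of which 2 also lost a call and 1 gained it. Leaving out spaceflight replicates 1 and 3 together gave 8 probe sets (7 of the 14), 6 genes (5 of the 10) and 11 lists (8 of the 18). Centring on the 75th percentiles gave 6 probe sets (3 higher, 3 lower), 5 of them at least 2-fold, and 3 genes. A threshold of 0.01 gave 4 probe sets and 2 genes, and a threshold of 0.1 gave 24 probe sets and 16 genes. A 1.5-fold limit gave 14 probe sets. Including the control identifiers gave 8 probe sets. The mean of a gene's probe sets gave 16 genes, as did single-gene probe sets only. Lists numbered 7 with probe sets above the median level, 0 with an estimated correlation and 2 with fry.

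Leaving out each array in turn gave 4 to 13 probe sets, 4 to 12 at least 2-fold, 2 to 9 genes and 12 to 20 lists. The gene count was 5, 6 and 3 without spaceflight replicates 1, 2 and 4, and 4, 2, 2 and 2 without ground-control replicates 1 to 4.

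The replicate block gave 0 probe sets, 0 at least 2-fold and 0 genes, with limma's smallest adjusted p at 0.0518 and 2446 probe sets at an unadjusted p under 0.05. The labels do not say whether the numbers pair the mice. Deviations of same-numbered arrays correlated at 0.251, -0.397, -0.287 and 0.0960, and 0 of 4 spaceflight arrays correlated best with its own number. Spaceflight replicates 1 and 3, of narrower range, both correlated best with ground-control replicate 2, and replicates 2 and 4 with ground-control replicate 3. Such array-wide differences can hide a pairing, so these correlations cannot exclude one.

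Directions turned for some lists, of which extracellular matrix and antioxidant response had been called as lower with all arrays. Without both spaceflight replicates 1 and 3 the means were 0.12 for MHC class II, 0.0545 for T cell receptor signalling, 0.0591 for extracellular matrix, 0.0166 for antioxidant response, 0.0384 for double-negative thymocytes, 0.15 for dendritic cells and macrophages (then called as higher), 0.12 for B cells, 0.0478 for fibroblasts, 0.0645 for endothelium and 0.0302 for parathyroid and thyroid. T cell receptor signalling was at 0.0309 with 75th-percentile centring, the clock list at -0.0213 above the median level, and the lymph node list at -0.00609 with median centring and -0.00281 with repeated quantile normalization. Leaving out single arrays gave -0.19 to 0.00050 for cell cycle, -0.0884 to 0.0259 for T cell receptor signalling, -0.21 to 0.0704 for endothelium and -0.11 to 0.0789 for lymph node. Alternatives on probe set suffixes were not run, because the identifiers are plain numbers. Signal over background limits dim genes, which were filtered only in the level alternatives.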

Other observations

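The tests of the 2 arrays that stand apart, of fat cells without replicate 1, of splits for the 3 counts of probe sets and genes, and of splits for fry's mixed p were chosen only after related results had been seen, as were the fatty acid synthesis, fat marker, airway, squamous and liver lists.

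Genes of fatty acid synthesis were lower after spaceflight. In a list written after the falls of Acly, Acaca, Me1, Thrsp, Tkt, Acss2 and Insig1 were seen, and which includes them, 19 of 23 measured genes fell when adjusted over the list alone, and 1, Acly, over all genes. Thrsp, a regulator of lipogenesis, fell by 1.21, Acss2, which makes acetyl-CoA from acetate, by 1.05, Me1, a source of NADPH, by 1.30 and Tkt, an enzyme of the pentose phosphate pathway, by 0.75. The list mean was -0.70 ± 0.14 (exact permutation p = 0.0286, the smallest possible; camera p = 9.22e-22 and p = 0.0133 with an estimated correlation, both unadjusted). Without the 7 genes that prompted the list, 11 of the remaining 16 fell when adjusted over those 16 alone, with a mean of -0.53 ± 0.13 (exact permutation p = 0.0286; unadjusted camera p = 2.04e-11, and p = 0.0263 with an estimated correlation). Insig1 is also on the cholesterol list, Me1 on the antioxidant list, and Elovl3 and Scd1 on the fat cell list.

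Liver transcripts were found in the ground-control lobes at very different levels. Albumin (Alb) was at 6.10, 7.79, 8.88 and 9.95 in ground-control replicates 1 to 4 and between 4.88 and 5.46 in the spaceflight arrays. Of 14 liver genes, 4 were lower when adjusted over the list alone (Alb, Serpina1c, Apoc3 and Ttr), with a list mean of -0.81 ± 0.29. The list was written after Alb and Serpina1c were seen. Without these 2 genes, 1 of the remaining 12 was lower when adjusted over those 12 alone, and the mean was -0.53 ± 0.20. The exact permutation p was then 0.0857, and the unadjusted camera p was 5.87e-06, or 0.0838 with an estimated correlation. A difference of liver genes as a group was therefore not established. Alb had a limma adjusted p of 0.187 over all genes. The whole list had an exact permutation p of 0.0286 and an unadjusted camera p of 7.79e-08, or 0.0748 with an estimated correlation. Of its members, 0 passed without spaceflight replicates 1 and 3.

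Heat shock genes were lower and Rbm3 and Cirbp higher in spaceflight. The 2 arrays that stand apart were argued against as the whole cause, since the heat shock mean without both was -0.50, 76.5% of its size. A part stays open, because the mean moved toward 0 by more than its SE of 0.12. Time of day at collection cannot be told apart from the flight. The 10 rhythmic clock genes differed by a median of 0.38 in size (95% bootstrap interval over genes 0.22 to 0.50). That median lies between the values that would have pointed to or against time of day. A lower body or tissue temperature before collection, or the flight itself, may also be the source, and neither was tested.

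For the fall of fatty acid synthesis genes, fewer fat cells in the spaceflight lobes cannot be told apart with all arrays, because fat markers outside the pathway (mean -0.41 ± 0.27, 4 of 20 lower when adjusted over the list alone) lay at a median only 0.25 above it (95% bootstrap interval 0.05 to 0.54). That rested on replicate 1. Without it the gap was 0.497 (0.18 to 0.84), with fat markers at a median of -0.12 and the pathway at -0.62. For the pathway list as written, this argues against fewer fat cells as the whole cause in replicates 2, 3 and 4, and a part stays open. Both intervals are over genes and do not measure spread between mice. The pathway list also includes the 7 genes that prompted it, which can widen the gap. Without these genes the pathway mean with all arrays was -0.53, closer to that of the fat markers. The gap itself was not computed without them. Among fat markers outside the pathway, 4 still fell and 1 rose, adjusted over the list alone, without spaceflight replicates 1 and 3. The 2 arrays that stand apart were argued against too, since the pathway's median without both was -0.77, 109% of its size. Feeding state and the flight itself stay open as untested, so the pattern may be biological only as a hypothesis.

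The 8 arrays can be split 4 against 4 in 35 ways. Only the real split gave 14 probe sets, 9 at 2-fold and 10 genes (highest other 0 for each). This argues against chance as the source of these counts but cannot exclude it. A result of 1 in 35 is the strongest the test can give, and it was chosen after the counts were seen. The other splits also mix the groups, which adds any real difference to their spread. The 18 lists called by camera may be a product of chance or of the 2 arrays that stand apart. Of the 35 splits, 9 gave as many and the highest other gave 22. Each split that gave 22 had spaceflight replicates 1 and 3 on the same side, as the real split has. A split with 19 lists had them on opposite sides. Some of these splits also kept most spaceflight arrays together, so they are not free of the real difference. For the clock list, singled out of 32 by its mixed p of 1.08e-07, the other splits gave that list no p under 0.0793. Over all 32 lists, only 1 of the 35 splits, the real one, had a smallest mixed p as small, but another split reached 5.05e-07 with some list. The margin is narrow, so a change of the clock list stays a hypothesis.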
